A study of Mus musculus with 9 samples.

How the data were processed

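RNA from mouse embryonic stem cells was sequenced in 9 samples, and the 6 libraries of the wild-type and Sirt6 knockout groups (3 each) were used; columns were matched to samples by name, and groups and replicate numbers came from the sample titles. The 3 glucose-deprived libraries were not analysed here, so the comparisons planned with them were not made, and the planned fit over all groups became a fit over 6 libraries. The labels do not say that replicates were separate cultures; p-values measure only the spread between these samples, which may be technical.

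The deposited count table gives whole-number counts per gene symbol in 23366 named rows, with no normalization. The submitters' processing notes list TopHat2 2.0.10, HTSeq 0.6.1, DESeq2 and the build mm9, with no role or order; the strand setting, annotation and filters are not given in the sources used here. A second table holds the authors' own comparison of knockout with wild type for 19025 genes. Per the file headers it gives a base mean signal, a log2 fold change with its standard error, a score (the Wald statistic), a p-value and an adjusted p-value, as DESeq2 writes them; those values are quoted only where the authors' deposited table is named. In that table, 725 genes had no adjusted p. Symbols in 27 rows had turned into dates, and these rows were kept but not named.

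Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, a mean per group, TMM factors), after filterByExpr with default settings, which left 14988 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are edgeR's fitted values, and the standard error given beside each is its size divided by the square root of F. CPM values use TMM-scaled library sizes. The 38 gene lists, the naming rule and most of the alternatives were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Their p-values were adjusted over the 38 lists. The test was repeated with a correlation estimated per list, with which 0 of the 16 called lists passed. For the cholesterol list the estimate was -0.00366, below the preset, yet its unadjusted camera p went from 4.27e-06 to 0.00740. The estimated correlation is therefore not the only difference between these forms of the test. Lists were also tested with fry, which asks whether a list's genes move one way on balance and compares them with no other genes. Named genes were Sirt6, the 10 largest rises and 10 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups (symbols that are model numbers passed over), and up to 4 called members per list with the smallest adjusted p; any other gene named was chosen after its values were seen.

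The total count per library ran from 20107037 to 29267115. A group count of 0 was set against a floor of 3 counts over the group, and ratios with 1 to 3 counts carry exact 95% intervals; these cover counting error only. Genes that share reads with near-identical copies or with overlapping or antisense genes are uncertain, since the counting rules were not stated. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 3.92).

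On simulated counts, 50 genes with a mean of at least 1 CPM in wild type were changed at each fold. The edgeR test recovered 58% at 1.5-fold, 96% at 2-fold and 100% at 4-fold and 8-fold among 14274 genes tested. Of its calls, 3.28% were unchanged genes. Far fewer genes were changed there than in the real comparison, where 55.7% were called, so these shares need not hold for it. Chromosome, transcript length and GC content came from a GRCm38 annotation (GENCODE M21), matched by symbol for 21706 rows and by an older symbol for 1272; this build is not the authors', so no coordinates are given and only names, chromosomes and gene order were used. Length and GC content were known for 98.9% of tested genes. Intervals of medians are order-statistic intervals over genes, which are not independent replicates.

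The alternatives were DESeq2 size factors and total counts as scaling, no filter and a mean of at least 1 CPM as filters, DESeq2 1.42.0 and limma-voom as tests, the replicate number as a block, each replicate left out in turn, a log2 fold minimum of 1 and an adjusted p under 0.01. Removal of each library's trend on transcript length and GC content, a fit without chromosomes 1, 8, X and Y, and library sizes without Rn45s, Rmrp and Rpph1 were added after the data were seen.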

Results

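Gene expression was measured by sequencing of total RNA from mouse embryonic stem cells. The cells were of the 129 SvJae F1 strain at passage 21, grown in serum with leukaemia inhibitory factor (LIF). The series lists 9 samples in 3 groups of 3: wild-type cells, cells lacking the histone deacetylase gene Sirt6, and wild-type cells deprived of glucose. The 6 wild-type and knockout libraries were compared, and the 3 glucose-deprived libraries were not analysed here. Total counts were 27785052, 25044061 and 27120905 in wild-type replicates 1 to 3 and 29267115, 23220037 and 20107037 in knockout replicates 1 to 3. Across genes, log2 CPM (counts per library, scaled to its size) correlated at 0.994 to 0.995 among the wild-type libraries, 0.985 to 0.993 among the knockout libraries and 0.928 to 0.939 between the groups (genes are not independent replicates). The 45S ribosomal precursor Rn45s took 8.62% ± 0.936 of the counts in wild type and 3.97% ± 0.833 in the knockout (SD, n = 3). The abundant noncoding RNAs Rmrp and Rpph1 did not pass the test (log2 fold change 0.59 and 0.61).

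The comparison of knockout with wild type asks which transcripts differ when SIRT6, which the series title ties to promoter-proximal pausing of RNA polymerase II, is missing. Sirt6 itself fell from 13.5 ± 0.690 CPM to 0.308 ± 0.0664 CPM (SD, n = 3), 42.2-fold, in the direction of the labels. Its counts were 348, 341 and 342 in the wild-type libraries and 12, 6 and 6 in the knockout libraries. Of 14988 genes tested, 4182 rose and 4163 fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 8345 in all or 55.7%. A log2 fold change of at least 1 in size was reached by 1889 of the higher and 1349 of the lower genes. The groups did not overlap in 63.2% of tested genes, where chance gives 10% for 3 against 3, and 8169 of the changed genes showed no overlap. The common biological coefficient of variation was 0.115. With total counts in place of the trimmed mean of M values (TMM), which moves the median of all genes by 0.13 (log2), 5114 genes rose and 3101 fell, so that 62.3% of calls were higher in the knockout against 50.1%. In the authors' deposited table, 8378 genes passed an adjusted p of 0.05, 4349 higher and 4029 lower. Of these, 7833 were called in both analyses with the same sign and 0 with opposite signs, and Sirt6 had a log2 fold change of -5.05.

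The genes that fell furthest included developmental regulators and imprinted genes. Nkx6-3, a homeobox gene, fell from 49.2 ± 1.70 to 0.515 ± 0.168 CPM (95.1-fold), and the imprinted gene Mest from 107 ± 3.46 to 2.74 ± 0.313 CPM (39.1-fold). Ccnd2, which encodes cyclin D2, fell 18.7-fold from 35.6 ± 1.62 to 1.89 ± 0.0908 CPM. The remaining large falls were Plagl1 (log2 fold change -4.90), the endocytic receptor gene Cubn (-4.73), Msln (-4.46), the neural regulator Sox21 (-4.46), Lims2 (-4.10) and the ankyrin gene Ank1 (-3.97). The genes that rose furthest were silent or nearly silent in wild type. Efhc2, on the X chromosome, rose from 0.197 ± 0.0427 to 45.3 ± 6.18 CPM (225-fold), Fmr1nb from 0.787 ± 0.260 to 29.7 ± 9.55 CPM (37.0-fold) and Fndc3c1 from 0.338 ± 0.0408 to 10.7 ± 0.342 CPM (31.2-fold). Xlr3a had 2 counts over the wild-type libraries and 422 over the knockout libraries, a ratio of 212 with an exact 95% counting interval of 58.4 to 1759. It shares sequence with near-identical Xlr3 genes, as the Zscan4 genes do with each other, so their values are uncertain. The other large rises were Zscan4a (6.22), Itih5 (5.67), Snx31 (5.35), Zscan4c (5.28), the calcium-binding protein gene Calb2 (4.97) and Ptpn20 (4.81). Of these 10 rises, Efhc2, Xlr3a, Fmr1nb and Fndc3c1 lie on the X chromosome. Adjusted p-values of the named rises and falls ranged from 3.80e-09 for Mest to 2.22e-06 for Itih5 (edgeR).

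**Figure D1:**
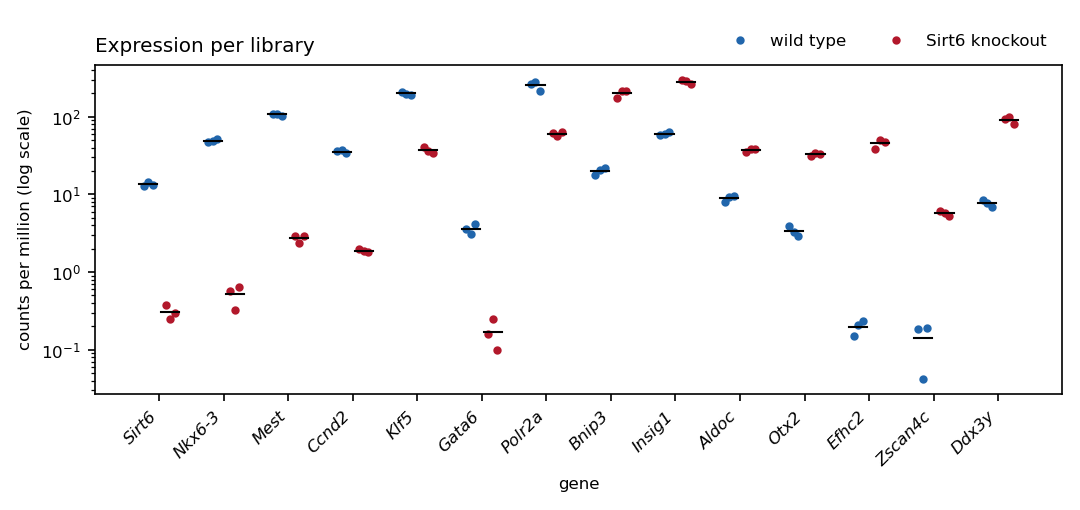
Scaled counts (CPM, log scale) of 14 genes in each of the 3 wild-type (blue) and 3 Sirt6 knockout (red) libraries; each point is a library and each bar the mean of a group. The wild-type and knockout points are separate for each gene shown, with Sirt6 at 13.5 against 0.308 CPM on average.

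Genes of glucose use, cholesterol synthesis and the hypoxia response rose as groups. Among 23 genes of glucose uptake and glycolysis, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.48. The aldolase gene Aldoc rose by 2.07 ± 0.11 (log2 ± SE), the phosphofructokinase gene Pfkp by 1.60 ± 0.10, the lactate transporter gene Slc16a3 by 1.71 ± 0.12 and the triosephosphate isomerase gene Tpi1 by 1.33 ± 0.12. The list passed the camera test (adjusted p = 0.000345), and not with an estimated correlation (adjusted p = 0.439). Among 20 genes of cholesterol synthesis and uptake, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.85 and an adjusted p of 8.11e-05 (adjusted p = 0.281 with an estimated correlation). Insig1, a sterol-sensing regulator, rose from 60.3 ± 2.84 to 283 ± 18.4 CPM (4.70-fold), and the biosynthetic genes Cyp51, Sqle and Nsdhl by 1.18 ± 0.09, 1.15 ± 0.09 and 1.23 ± 0.11. Of 20 hypoxia response genes 15 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 0.73 and an adjusted p of 0.000740 (adjusted p = 0.365 with an estimated correlation). Bnip3, a mitophagy gene, rose 10.1-fold to 201 ± 23.4 CPM. Ddit4, an inhibitor of mTORC1, and Ankrd37 rose by 2.02 ± 0.11 and 2.13 ± 0.20, and Aldoc belongs to this list too.

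Other metabolic lists did not pass as groups, though single members changed. Of 12 tested genes of gluconeogenesis and the pentose phosphate pathway, 5 rose and 3 fell (6 and 3 adjusted over the list alone, adjusted p = 0.644), with Taldo1 and G6pc3 up by 0.62 and 0.44 and Pgd and Fbp2 at -0.64 and -1.11. In the tricarboxylic acid cycle, 4 of 18 genes rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.477). Idh3g rose by 1.36 ± 0.11, Ogdh changed by -0.39 ± 0.10 (with total counts -0.26, not called, adjusted p = 0.0681), and the smaller calls of Dlst (0.29) and Sdhc (-0.37) were lost without several single replicates, at adjusted p-values of 0.0575 to 0.0855. For 42 nuclear-encoded respiratory chain genes, 0 rose and 5 fell (0 and 2 adjusted over the list alone, adjusted p = 0.750), the median being 0.03 and the mean -0.03 with the test pointing down. Without wild-type replicates 1 or 3 or knockout replicates 1, 2 or 3 that median was -0.00324, 0.0728, 0.228, 0.0194 and -0.209. Cox8a (-1.48 ± 0.17) and Uqcrq (-0.87 ± 0.19) fell, while the calls of Ndufs1 (-0.26) and Ndufb3 (-0.52) were lost without several single replicates, at adjusted p-values of 0.0725 to 0.137. With total counts the calls of Sdhc (-0.25, adjusted p = 0.0811), Ndufs1 (-0.14, 0.269) and Ndufb3 (-0.40, 0.0628) were lost, as was that of Ndufb3 with a mean of at least 1 CPM as the filter (0.0527). Ndufb3 was at -0.30 without knockout replicate 1, and Ndufs1 at -0.40 with the length and GC trend removed. Of 19 fatty acid oxidation genes 9 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.125), among them Acadvl (1.01 ± 0.10) and Slc25a20 (0.67 ± 0.11), with Acadl at -1.08 ± 0.13. Among the 5 glucose-responsive genes around thioredoxin-interacting protein, Txnip rose 2.64-fold to 303 ± 39.8 CPM, Arrdc4 by 0.78 ± 0.10 and Mlxipl by 1.35 ± 0.20, and Mlxip changed by -0.51 ± 0.11, or -0.24 with the length and GC trend removed (3 rose and 1 fell, and the same adjusted over the list alone, adjusted p = 0.358).

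Among the amino acid and stress response lists, the amino acid list passed as lower and the lysosome and autophagy list as higher. The others did not pass as groups. In the amino acid and integrated stress response list, 3 of 28 genes rose and 14 fell (4 and 14 adjusted over the list alone). Its median was -0.32 and its adjusted p 0.0360 (camera). The call ended with an estimated correlation (adjusted p = 0.498), without chromosomes 1, 8, X and Y (0.0993) and with the replicate block (0.0505). The transaminase gene Gpt2 (-1.59 ± 0.11), the cystathionine lyase gene Cth (-1.70 ± 0.12) and the amino acid transporter gene Slc7a5 (-1.47 ± 0.13) fell, whereas Ddit4 rose. Of 21 endoplasmic reticulum chaperone and unfolded protein response genes, 5 rose and 6 fell (4 and 6 adjusted over the list alone, adjusted p = 0.748). The median was 0.08 (0.1398 without knockout replicate 1 and 0.1288 without wild-type replicate 3), the mean -0.15 and the test pointed down. The chaperone genes Dnajc3 and Pdia3 and the transcription factor gene Xbp1 changed by -1.79, -1.20 and -0.70. The p53 target genes Trp53inp1, Btg2 and Plk2 rose by 1.60, 1.25 and 1.12, and 11 of 19 list members rose and 4 fell (11 and 4 adjusted over the list alone). That list missed the threshold at an adjusted p of 0.0736 and passed it without knockout replicate 2 (0.0435), with no filter on low counts (0.0460) and with a mean of at least 1 CPM as the filter (0.0492; range over 14 alternatives 0.0435 to 0.135). Of 14 heat shock and cytosolic chaperone genes 3 rose and 4 fell (3 and 4 adjusted over the list alone, adjusted p = 0.692), Hspd1 at -0.47 against Bag3 at 0.81 and Hspa1a at 1.54. In the lysosome and autophagy list 14 of 27 genes rose and 1 fell (14 and 1 adjusted over the list alone, median 0.34, adjusted p = 0.0474; adjusted p = 0.445 with an estimated correlation). Gabarapl1, Atg5 and Sqstm1 rose by 1.30, 1.25 and 0.86, and Tfeb changed by -1.10. Leaving out wild-type replicate 1, 2 or 3 or knockout replicate 3 ended this call (adjusted p = 0.0909, 0.0539, 0.0680 and 0.0666; range over 14 alternatives 0.0335 to 0.0909), as did the absence of a filter on low counts (0.0568), removal of the length and GC trend (0.0651) and the fit without chromosomes 1, 8, X and Y (0.0613). The replicate block ended this call as well (adjusted p = 0.0527, camera), and the list's median fell to 0.22 without knockout replicate 3. Of 13 tested immediate early genes 8 rose and 3 fell (8 and 4 adjusted over the list alone, adjusted p = 0.204), with Ier3, Klf6 and Jun up by 2.27, 1.13 and 1.65 and Myc at -1.81.

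Genes of naive and core pluripotency and of the endoderm fell, and genes of the primed epiblast rose. Of 30 pluripotency genes 7 rose and 18 fell (7 and 18 adjusted over the list alone), with a median of -0.46 and an adjusted p of 0.0294 (adjusted p = 0.365 with an estimated correlation). Klf5, a transcription factor of naive cells, fell 5.41-fold from 199 ± 10.2 to 36.7 ± 3.15 CPM, and Nr0b1, Gdf3 and Tbx3 fell as well (-1.15 ± 0.10, -1.25 ± 0.11 and -1.35 ± 0.12). Of 18 tested primed epiblast genes 12 rose and 3 fell (12 and 3 adjusted over the list alone, median 0.69, adjusted p = 0.00961; adjusted p = 0.439 with an estimated correlation). Otx2, a regulator of the primed state, rose 9.77-fold from 3.36 ± 0.515 to 32.9 ± 1.17 CPM, and Zic2, Zic5 and Cldn6 rose by 4.48 ± 0.24, 2.77 ± 0.17 and 2.07 ± 0.10. Among 16 tested genes of primitive and definitive endoderm 1 rose and 13 fell (1 and 14 adjusted over the list alone), with a median of -1.80 and an adjusted p of 8.11e-05 (adjusted p = 0.365 with an estimated correlation). The endoderm regulators Gata6 and Sox7 fell 20.7-fold and 12.9-fold, Cubn fell as above, and the laminin gene Lama1 fell from 214 ± 15.3 to 35.3 ± 8.27 CPM.

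Further lineage lists were mixed or held few expressed members. Of 9 tested neuroectoderm genes 4 rose and 5 fell (4 and 5 adjusted over the list alone, adjusted p = 0.477), with Pax6, Sox1 and Gbx2 at -2.85, -1.87 and -1.63 and Tubb3 up by 1.09. Of 10 tested mesoderm and primitive streak genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, adjusted p = 0.228): Bmp4 (-2.37), Tal1 (-3.80) and Gata2 (-2.11) fell, and Kdr rose by 1.69. With a mean of at least 1 CPM as the filter, this list passed (adjusted p = 0.0322, range over 14 alternatives 0.0322 to 0.780), as did the list of imprinted genes given below (0.0393, range 0.0393 to 0.317). In the trophectoderm list 7 of 10 tested genes rose and 2 fell (7 and 2 adjusted over the list alone, median 1.36, adjusted p = 0.0429; adjusted p = 0.365 with an estimated correlation). The keratin genes Krt18 and Krt19 rose by 2.28 and 2.34 and Tfap2c by 1.12, whereas the trophectoderm regulator Tead4 fell (-1.93). This call ended without wild-type replicate 3 (0.0586), without knockout replicate 1 (0.0879), with total counts (0.0722) and with the replicate block (0.0543). It also ended with no filter on low counts (0.160, median 0.89), with the length and GC trend removed (0.0651) and without chromosomes 1, 8, X and Y (0.0829). The range over 14 alternatives was 0.0255 to 0.160. Of 13 tested markers of embryonic fibroblasts, the usual feeder cells, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 2.41, adjusted p = 0.00522; adjusted p = 0.365 with an estimated correlation). Their levels stayed low: Tagln reached 21.7 ± 3.89, Col6a2 3.27 ± 0.248 and Acta2 2.46 ± 0.609 CPM in the knockout.

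Genes of the 2-cell-like state and the germline rose, and imprinted genes moved both ways. Of 12 tested genes of the 2-cell-like state, a rare condition in these cultures, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 4.50, adjusted p = 0.00208; adjusted p = 0.365 with an estimated correlation). Zscan4a, Zscan4f and Tmem92 rose from 0.0650, 0.133 and 0.0914 CPM to 5.24, 4.68 and 4.55 CPM. Among 21 tested germline genes 14 rose and 3 fell (14 and 4 adjusted over the list alone, median 1.13, adjusted p = 0.0127; adjusted p = 0.445 with an estimated correlation). Dazl, a germ-cell RNA-binding protein gene, rose 6.18-fold from 5.01 ± 0.166 to 31.0 ± 3.92 CPM, and Tex13, Slc25a31 and Sohlh2 rose by 4.06, 2.34 and 1.84. Of 28 tested imprinted genes 9 rose and 14 fell (9 and 14 adjusted over the list alone, adjusted p = 0.125), with Mest, Plagl1 and Peg13 at -5.29, -4.90 and -5.41 and Nnat up by 2.54. Of 5 tested Hox genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.216), among them Hoxb13 and Hoxd1, by 2.66 and 2.98 from low levels. Hoxd1 was at 6.81 without wild-type replicate 3. Of the 6 sex chromosome markers 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.204; median 2.13, also with Kdm5d at its bound). The Y-linked genes Ddx3y, Uty and Eif2s3y rose from 7.74 ± 0.791, 7.31 ± 0.534 and 24.8 ± 0.292 CPM to 91.5 ± 9.55, 38.1 ± 3.63 and 91.1 ± 14.2 CPM. The Y-linked gene Kdm5d had 0 counts in wild type and 191 in the knockout, at least 64.1-fold higher against a floor of 3 counts over the group. Xist fell 9.43-fold from 38.2 ± 6.23 to 4.06 ± 0.662 CPM. It overlaps the antisense gene Tsix, and the strand setting of the counting is not given in the sources used here.

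**Figure D2:**
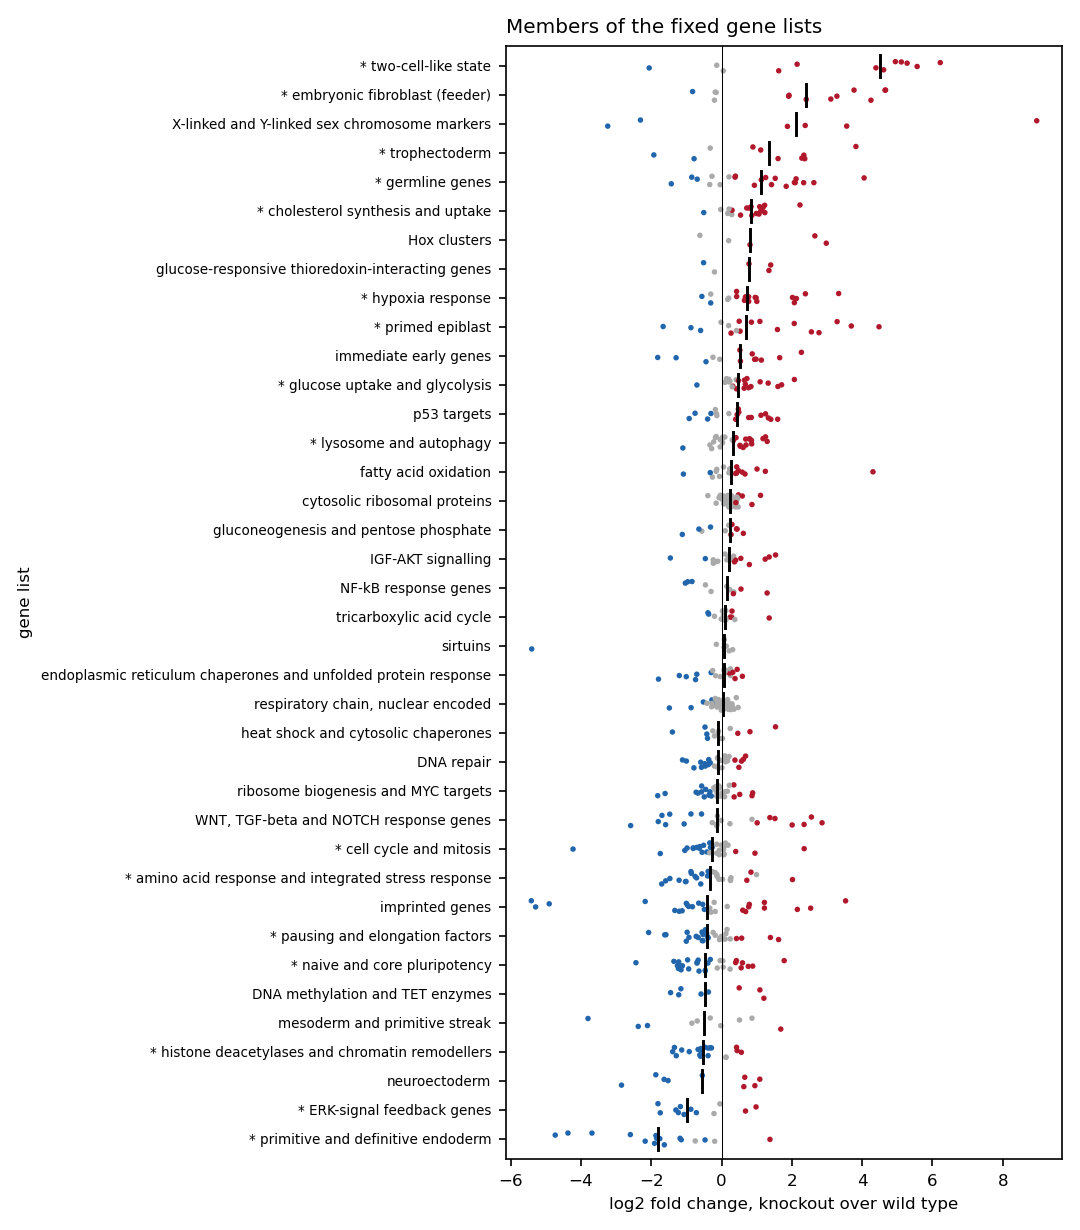
Log2 fold change (knockout over wild type) of each tested member of the 38 gene lists; each point is a gene, red where it rose, blue where it fell and grey where it did not pass an adjusted p of 0.05, and the black bar is the list's median. An asterisk marks the 16 lists that passed the camera test, of which the 2-cell-like list has the highest median (4.50) and the endoderm list the lowest (-1.80).

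Genes of transcription elongation, chromatin and the cell cycle fell. Of 32 pausing and elongation factors 4 rose and 18 fell (4 and 19 adjusted over the list alone), with a median of -0.41 and an adjusted p of 0.0294 (adjusted p = 0.548 with an estimated correlation). Polr2a, the largest subunit of RNA polymerase II, fell 4.21-fold from 253 ± 32.9 to 60.1 ± 3.07 CPM. Cdc73, of the PAF1 complex, fell (-1.62 ± 0.11), and the elongation factor gene Ell3 rose by 1.39 ± 0.11. Of 20 histone deacetylase and chromatin remodeller genes 3 rose and 15 fell (3 and 15 adjusted over the list alone, median -0.52, adjusted p = 0.0166; adjusted p = 0.522 with an estimated correlation). The Polycomb methyltransferase gene Ezh2 (-1.29 ± 0.11) and the acetyltransferase genes Ep300, Crebbp and Kat2a (-1.34 ± 0.13, -1.39 ± 0.13 and -0.92 ± 0.09) fell. Across all tested genes, the 20% with the longest transcripts had a median of -0.18, against 0.08 for the 20% with the shortest. All 8 tested DNA methylation and TET enzyme genes changed, 3 up and 5 down (3 and 5 adjusted over the list alone, adjusted p = 0.580): Dnmt3a and Dnmt3l rose by 1.09 and 1.20, and Tet2 and Tet3 fell (-1.22 and -1.45). Among 31 cell cycle and mitosis genes 3 rose and 16 fell (3 and 16 adjusted over the list alone, median -0.28, adjusted p = 0.0232; adjusted p = 0.439 with an estimated correlation). The D-type cyclin genes Ccnd1, Ccnd2 and Ccnd3 fell (-1.04, -4.22 and -1.74), and the inhibitor gene Cdkn2b rose by 2.35. Of 26 DNA repair genes 5 rose and 10 fell (5 and 10 adjusted over the list alone, adjusted p = 0.450), with Bard1 and Brca2 at -1.11 and -0.78 and Rbbp8 up by 0.69.

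Among signalling and growth lists, the feedback genes of ERK signalling fell. Of 12 tested ERK feedback genes 2 rose and 8 fell (2 and 8 adjusted over the list alone, median -0.97, adjusted p = 0.0153; adjusted p = 0.554 with an estimated correlation). Spry2 and Etv4 fell 3.35-fold and 3.50-fold from 213 ± 2.45 and 169 ± 4.54 CPM, and Spred1 and Spred2 fell too (-1.23 and -1.30). Of 22 WNT, TGF-beta and NOTCH response genes 7 rose and 8 fell (7 and 8 adjusted over the list alone, adjusted p = 0.750), the median being -0.12 and the mean 0.11 with the test pointing down. The median was -0.0760 without wild-type replicate 1 and -0.0787 without knockout replicate 3. Nkd1 rose by 2.35, and Hes1 and Id1 fell (-1.80 and -1.69). Of 19 tested IGF and AKT signalling genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.347), with Igfbp3, Igfbp2 and Igfbp4 up by 1.54, 1.24 and 1.36 and Foxo1 at -1.46. For 11 tested NF-kB response genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, adjusted p = 0.948; median 0.15, mean -0.06, test pointing down), among them Nfkb1, Bcl3 and Sod2 at -0.96, -1.03 and -0.84 and Tnfaip3 up by 1.30. Of 34 ribosome biogenesis and MYC target genes 5 rose and 11 fell (5 and 11 adjusted over the list alone, adjusted p = 0.216). Ncl and Myc fell (-1.60 and -1.81), and Mycn and Odc1 rose by 0.87 and 0.89. Of 59 tested cytosolic ribosomal protein genes 5 rose and 0 fell (1 and 0 adjusted over the list alone, adjusted p = 0.127), with Rpl10 and Rps12 up by 1.11 and 0.87. The calls of Rpl15 (0.48) and Rps16 (0.59) were lost without several single replicates, at adjusted p-values of 0.0501 to 0.111. Without knockout replicate 3 these values were 0.30 and 0.34, and with the length and GC trend removed Rpl15 was at 0.26. That list rested on single libraries: its adjusted p was 2.71e-05 without knockout replicate 1 and 0.996 without knockout replicate 3, the lowest and highest of 14 alternatives. Of the 7 sirtuins, Sirt6 alone passed the test, adjusted over all genes or over the list alone (adjusted p = 0.947; median 0.08, mean -0.67, test pointing down). The median was 0.154 without wild-type replicate 1 and 0.0445 without knockout replicate 3.

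Fold changes also differed by chromosome, with gene order taken from the GRCm38 assembly. Tested genes on chromosome 1 had a median of -0.30 (813 genes, 95% interval -0.36 to -0.23; 144 rose and 375 fell) and those on chromosome 8 a median of -0.24 (788 genes, -0.28 to -0.18; 148 rose and 332 fell). Chromosome X had a median of 0.20 (539 genes, 0.11 to 0.28), and all 6 tested Y-linked genes rose. A running median over 25 neighbouring genes passed the limits that 1 in 20 of 300 shuffles of the gene order passed (-0.75 and 0.88) in 8 runs of at least 10 genes, found after the values were seen. From Men1 to Stxbp3b on chromosome 19, 61 of 69 tested genes fell and 1 rose (median -1.01), and from Elf1 to Slc15a1 on chromosome 14, 47 of 51 fell and 1 rose (median -1.50). Klf5, Spry2, Sox21 and Dnajc3 lie in the chromosome 14 run, Cox8a in the chromosome 19 run, Zscan4a in a chromosome 7 run and Idh3g in an X-linked run. Outside the 8 runs, 4140 genes rose and 4015 fell. In a fit without chromosomes 1, 8, X and Y, added after the data were seen, 6998 genes changed, and 7 of the 16 list calls ended: pluripotency (median -0.45), germline (1.01), pausing and elongation (-0.40), and cell cycle (-0.16), at an adjusted p of 0.0687 each, lysosome and autophagy (0.0613, median 0.63), trophectoderm (0.0829, median 1.09), and amino acid and integrated stress response (0.0993, median -0.28). Over the 14 alternatives, the adjusted p of the pluripotency and elongation lists ranged from 0.00885 to 0.0687, of the germline list from 0.00576 to 0.0687, of the cell cycle list from 0.00751 to 0.0687 and of the stress response list from 0.0117 to 0.0993.

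**Figure D3:**
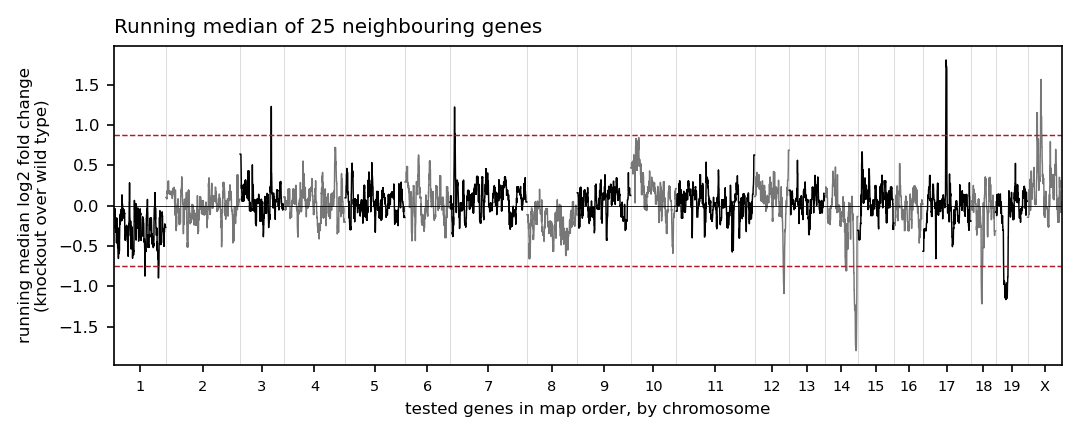
Running median of the log2 fold change (knockout over wild type) over 25 neighbouring tested genes, in map order along chromosomes 1 to 19 and X; alternating shades mark chromosomes and the dashed lines the limits of -0.75 and 0.88 from 300 shuffles of the gene order. Chromosomes 1 and 8 lie below 0 over most of their length, and chromosomes 1, 12, 14, 18 and 19 dip below the lower limit, chromosome 14 furthest.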

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

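The fits without the length and GC trend, without chromosomes 1, 8, X and Y and without Rn45s, Rmrp and Rpph1 were chosen after the data were seen; a fit of the 6 libraries alone is the fit reported, and alternatives for the glucose-deprived samples were not run. Sirt6 stayed lower and past the threshold in each setting. The count of changed genes, 8345, lay between 7473 and 9968 with the other scalings, filters, tests and the length and GC trend removed, was 6385 at an adjusted p under 0.01 and 6998 without the 4 chromosomes, and moved to 3238 with a log2 fold minimum of 1, which by construction keeps fewer genes. Leaving out each replicate in turn gave 6986 to 9876 genes. Same-numbered libraries deviated together with correlations of 0.208, -0.0250 and 0.201, and the replicates numbered 2 did not correlate best with each other. Wild-type replicate 1 with knockout replicate 3 gave -0.207, and wild-type replicate 3 with knockout replicate 1 gave -0.216. Deviations from a mean of 3 libraries sum to 0, so a trend over replicates 1 to 3 leaves replicate 2 near 0. Whether the numbers pair the samples is therefore not settled. The replicate block gave 9352 genes, 8307 of them called with the same sign without it, and 14 lists. It took the lysosome (adjusted p = 0.0527), trophectoderm (0.0543) and stress response (0.0505) lists over the threshold and the ribosomal protein list under it (0.0463). Against 16 called lists, 9 passed without the 4 chromosomes, where the list of sex chromosome markers could not be tested. Of the 38 lists, 0 passed with an estimated correlation and 30 with fry, which asks a different question. The cause of the other changes was not tested. Without each replicate in turn, 14 to 17 lists passed. Among named genes under the alternatives, 2445 values kept direction and side of the threshold, 28 lost the call and 0 changed direction. Named genes were picked for large changes or small adjusted p-values, so this need not hold for all calls. Of the 8345 calls, 7283 kept call and sign with total counts and 6837 without wild-type replicate 1. For lists under the alternatives, 539 values kept direction and side of the threshold, and 37 lost and 21 gained the call. A further 9 changed direction in the test, in lists not called. Those had medians of 0.108 (sirtuins, at least 1 CPM), 0.119 (sirtuins, without knockout replicate 2), 0.228 (respiratory chain, without knockout replicate 1, against -0.209 without knockout replicate 3), 0.00495 (ribosomal proteins, without knockout replicate 3, against 0.480 without knockout replicate 1), -0.124 (WNT, TGF-beta and NOTCH, fry) and, for NF-kB, 0.231 (no filter), 0.219 (at least 1 CPM), 0.143 (without knockout replicate 3) and 0.177 (length and GC trend removed). The cause was not tested. The lowest and highest medians on leaving out a replicate were 0.0445 and 0.154 for sirtuins (knockout replicate 3 and wild-type replicate 1 left out) and 0.111 and 0.172 for NF-kB (wild-type replicates 3 and 1 left out). Depth limits genes near 1 CPM or below. The 58% recovery of 1.5-fold changes on simulated counts covers only genes with a mean of at least 1 CPM in wild type.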

Other observations

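Some gene families other than the fixed lists, though a few members such as Cldn6, Col6a2 and Rtl1 are in both, held many changed genes, in a comparison where 55.7% of tested genes changed. They were picked after their values were seen, so their counts carry no test as groups. Guanylate-binding protein genes, which interferon induces, rose in 6 of 7 cases, with Gbp2 going from 0.342 ± 0.0665 to 8.22 ± 0.931 CPM (SD, n = 3) and Gbp9 from 0.477 ± 0.409 to 6.25 ± 0.679 CPM. These genes share sequence and their values are uncertain. On chromosome 17, 10 of 10 tested genes of MHC class II presentation and peptide loading in a single run rose (median log2 fold change 2.96). Among them were the immunoproteasome genes Psmb8 (0.0532 to 2.71 CPM) and Psmb9 (1.25 to 7.95 CPM) and the peptide transporter gene Tap2 (0.367 to 3.28 CPM). The whole run, from Col11a2 to Btnl6, was picked for being high. It held 17 tested genes, of which 15 rose and 1 fell. Collagen genes rose in 20 of 31 cases and fell in 5. Those that fell included the basement membrane genes Col4a1 (79.7 to 25.7 CPM) and Col4a2 (35.5 to 9.62 CPM), both on chromosome 8. Tetraspanin genes rose in 13 of 19 cases and fell in 1, claudin genes rose in 7 of 12 and fell in 1, and axonemal dynein heavy chain genes rose in 8 of 10 and fell in 2.

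Among families with more lower than higher genes, all 9 tested CHD remodeller genes were lower, from -0.38 for Chd1 to -1.92 for Chd3 in log2 fold change. Of 18 hnRNP genes, which encode RNA-binding proteins of splicing, 12 fell and 0 rose (median -0.52), with Hnrnpd at -1.66 ± 0.09 and Hnrnpa3 at -1.87 ± 0.10 (log2 ± SE). Of 9 tested MCM genes, most of them subunits of the replicative helicase, 7 fell and 1 rose (median -0.51). The lowest, Mcm5 (-0.80), lies on chromosome 8, and Mcm6 (-0.71) and Mcm3 (-0.63) lie on chromosome 1, both lower as a whole. Mcm2, Mcm4, Mcm9 and Mcm10, on other chromosomes, fell too. Of 22 gamma protocadherin genes 21 fell (median -1.49); these genes share their last exons, so their counts are not independent. Of 11 WNT ligand genes 6 fell, Wnt6 (on chromosome 1) from 4.62 to 0.613 CPM, and 2 rose. On chromosome 12, 12 of 17 neighbouring genes fell in a run from Rtl1 to Mir300 (median -1.20), which holds the imprinted genes Rtl1 and Rian.

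The 8345 changed genes belong to 1 of the 10 splits of the 6 libraries into 3 and 3, the real one; the highest of the other splits gave 0 genes, and 10 splits are too few for a share under 0.05.

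For the elongation and chromatin genes, of whose 32 and 20 members 18 and 15 fell, removal of the length and GC trend was chosen only after the result was seen. With the length and GC trend of each library removed, the median of the 40 called members was -0.44 against -0.54, and 39 kept their call and sign. These 40 were picked by their call in the same data, which favours that outcome. Over all 32 and 20 members, the medians were -0.34 and -0.40 with the trend removed, against -0.41 and -0.52. This argues against that trend as the whole cause. Lower RNA integrity in the knockout stays open: the mean slope on transcript length was lower in the knockout by a difference of -0.0691 per doubling, but knockout replicate 1 (0.0906) lay above the wild-type libraries (0.00291 to 0.0670) and knockout replicates 2 and 3 below them (-0.0423 and -0.152). The called members had medians of -0.38, -0.53 and -0.72 in knockout replicates 1 to 3. An effect of losing Sirt6 on these genes remains a hypothesis, and other differences between the cell lines were not tested apart from it.

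Of the tests here, removal of the length and GC trend, the test of X-linked genes and those of copy loss in the runs were chosen only after the result was seen, and the chromosome shifts may reflect differences between the cell lines other than Sirt6. With the length and GC trend removed, the higher of the medians of chromosomes 1 and 8 was -0.23, below the lowest of the other autosomes, and the higher of the medians of the chromosome 14 and 19 runs was -1.07, which argues against that trend as the cause. A loss of 1 of 2 copies of the chromosome 19 run would put its median at -1, and it was -1.01 (95% interval -1.22 to -0.88) with values of -1.02, -1.09 and -0.91 in the knockout replicates, though the run was picked for being low and RNA alone gives no copy number; the chromosome 14 run, at -1.50 (-1.77 to -1.23), lay below what such a loss alone would give. A copy number difference of the whole of chromosomes 1 and 8 cannot be told apart from other causes. With each split into 4 equal stretches, the 8 medians ran from -0.35 to -0.12, against a median of 0.045 over the stretches of other autosomes. Only 4 of the 8 lay below the bound that 95% of those other stretches exceed (-0.2704). The last stretch of chromosome 8 (-0.2703) narrowly missed it. The lowest of the other stretches lay on chromosomes 19 (-0.66), 14 (-0.48) and 18 (-0.27), which also hold runs of lower genes. They set the bound, so this count cannot tell a patchy shift from one over whole chromosomes. A change from 3 copies to 2 in all cells would give -0.58, further from 0 than the medians of -0.30 (chromosome 1) and -0.24 (chromosome 8). For the Y-linked rise and the fall of Xist, 2 active X chromosomes in the wild-type cells would lower X-linked genes in the knockout, and their median was 0.20 (0.11 to 0.28). The Y-linked genes Kdm5d and Zfy1 had 0 counts over the wild-type libraries, against 191 and 66 over the knockout libraries. The Y-linked pattern, too, may reflect a difference between the cell lines other than Sirt6, which was not tested.

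For the markers of embryonic fibroblasts, higher in the knockout, the test of feeder cells and the removal of the length and GC trend were chosen only after the result was seen. Feeder cells carried into the knockout libraries stay open as a candidate source. Of Col3a1, Lum, Dcn and Postn, the highest was Col3a1, at a ratio of 0.205 to Col1a2 in the knockout. That ratio includes the baseline of Col3a1, which had 8 counts in wild type and 9 in the knockout. Lum had 0 counts in each group, and Dcn and Postn had 5 each in the knockout. Col1a2 had 46 there, Col1a1 163, Acta2 180 and Thy1 402. Col3a1, Lum, Dcn and Postn thus did not reach the level of Col1a2, which speaks against feeder cells, but counts this near the floor do not settle it. Fn1 and Sparc, which these stem cells also express, were lower in the knockout (346 against 559 and 76.2 against 159 CPM scaled by total counts), and a high baseline of this kind would hide a small share of other cells. The length and GC trend is argued against, as the median of all 13 tested members was 2.46 with it removed against 2.41. For the 10 called members, picked by their call in the same data, it was 3.24 against 3.20. A higher expression of these genes in the stem cells themselves was not tested.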
